A study of Sus scrofa with 30 samples.

How the data were processed

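Gene expression was measured on Affymetrix porcine GeneChip arrays in the brachial artery and the femoral artery of Rapacz hypercholesterolemic swine, a strain with inherited high blood cholesterol. There were 30 arrays from 15 pigs: 4 pigs aged 1 week, 6 aged 1 year and 5 aged 2 years, with both arteries taken from each pig. The labels state that RNA of the piglets was isolated on columns alone and that RNA of the older pigs went through a caesium chloride centrifugation step before the column. They name the material of every sample as whole blood in a separate field, although the titles and the study design name arteries, and the samples were taken as arteries here. The sex of the pigs is not in the labels.

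The deposited table holds log2 values for 19459 probe sets on each array. The submitters' processing notes name GCOS 1.4, R 2.3.1 and RMA, without a version for RMA, and which step each did is not given in the sources used here. The log2 scale was inferred from the deposited values, which ran from 2.65 to 15.1 with nearly equal medians in all arrays, and they were taken as RMA values. No scanner files were used, so background correction and probe summary were not repeated.

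The 97 control probe sets were left out of the tests, and 19362 probe sets were tested with no filter on low values. Gene symbols came from the annotation of the array, matched by probe set. A single symbol was given for 8541 probe sets, several for 165 and none for 10656. This gave 6054 named genes, each represented by the probe set with the highest mean over the 30 arrays. No genome assembly was used, so positions are not given.

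Whether the arrays of a pig belong together was checked before pairing them. After the mean of each group was subtracted, each of the 15 pigs' arrays correlated best with the other artery of the same pig (r = 0.114 to 0.877, across probe sets, which are not independent replicates).

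Tests used limma 3.58.1 in R 4.3.3, with jsonlite 2.0.0 to read the labels, and figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. The arteries were compared within pigs, with the pig as a fixed block, over all ages and as a separate artery effect for each age with a shared spread. The test of artery by age asked whether the artery effect differed between any of the 3 ages, on 2 degrees of freedom. Ages were compared between pigs on each pig's mean over its 2 arteries, with the pig as the replicate. All tests were two-sided, with Benjamini-Hochberg adjustment over the 19362 probe sets, and a probe set was called at an adjusted p under 0.05. The ± values beside log2 fold changes are standard errors from these fits. The number of arrays limits the precision of the values.

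The rule for naming genes was set before the data were examined. For the artery comparison over all ages, and for 1 year against 1 week and 2 years against 1 year, the 10 called genes with the largest log2 fold change in each direction were named. The artery comparison also asked for the same direction in at least 12 of the 15 pigs. For the other comparisons the 4 largest in each direction were named, and for the test of artery by age the 8 with the smallest adjusted p. HOX genes, APOB, ACTA2 and NOS3 were named whatever their values. TBX4, TBX5, PITX1, MYH11 and ELN were to be named too, but no probe set carried the symbol alone, and they were not analysed here.

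Gene lists for vascular, immune and metabolic groups were also set before the data were examined, from textbook knowledge. They include markers of cell types that a dissected artery can hold: endothelial, smooth muscle contractile, macrophage and monocyte, lymphocyte, erythroid and platelet blood, skeletal muscle, adipocyte, Schwann and nerve, and adventitial fibroblast. The 32 lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the 32 lists. This asks whether a list's genes ranked above or below the other named genes. Camera with a correlation estimated from the data, fry and camera on every probe set were run beside it. Fry asks another question, whether a list's genes shifted in a shared direction, without regard to the other genes. Members that move in opposite directions can offset each other in it. A fry value is therefore not the same test of a list. Up to 4 members of a list were named, those with the smallest p. Measures of single arrays, such as control signals and the mean of a list, were compared with exact permutation tests.

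The procedure was tested on simulated data with the same 15 pigs and 19362 probe sets, of which 200 were changed. For femoral against brachial over all ages, 94.5% of the changed probe sets were recovered at a log2 change of 0.5. For the artery effect at 1 week, 1 year and 2 years it was 60%, 89.5% and 78%, and for artery by age 41%. For 1 year against 1 week, 2 years against 1 week and 2 years against 1 year it was 66%, 59% and 66%. At a log2 change of 1, recovery lay between 90.5% and 100% in all of these comparisons. Of the probe sets called, the share that had not been changed was lowest for the artery effect at 1 week (1.64%, at a log2 change of 0.5). It was highest for the artery effect at 1 year (7.83%, at a log2 change of 1). This share exceeded the adjusted p threshold in some comparisons, such as femoral against brachial over all ages (6.44% and 6.98%), and lay below it in others. With no change simulated, 0 probe sets were called in each comparison. Noise was drawn independently for each probe set, with the same spread at every age. The simulation thus leaves out correlation between genes and unequal spread between ages, and its 0 does not measure false calls in the real arrays.

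Alternatives were quantile normalization applied again, a shift of each array to a shared median, removal of the lowest 25% or 50% of probe sets, an intensity trend with robust moderation, array weights, and each pig left out in turn. For the arteries they were also a fit without the pig block, the pig as a random block, the number in front of each title as a covariate, and a fit to each age alone. For the ages they were 30 arrays with the pig as a random block, each artery alone, and the compared ages alone. A pair of alternatives was chosen after seeing the data: leaving out pigs 9994, 9995 and 9997, and adding the 3' minus 5' signal of the beta actin control probe sets as a covariate. Leaving out those pigs keeps only pigs 9006 and 9007 at 2 years, so calls can also end for lack of pigs.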

Results

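The data set held 30 arrays from 15 Rapacz hypercholesterolemic swine, with a brachial and a femoral artery from each pig. There were 4 pigs aged 1 week, 6 aged 1 year and 5 aged 2 years. The arrays had nearly equal medians, and the mean of the medians of a group lay between 8.08 (brachial, 2 years) and 8.12 (femoral, 1 year) on the log2 scale. Expression was compared between the arteries within pigs, and between ages with the pig as the replicate.

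The principal components followed age and then artery. PC1 held 41.5% of the variance and PC2 23.2%, and PC3, with 5.53%, separated the arteries. The mean PC3 score was lower by 23.1 in the femoral artery, with a mean of -11.5 against 11.5 in the brachial (exact paired permutation test, two-sided, p = 6.1e-05, the smallest it can give, adjusted p = 0.00586, n = 15 pigs). The 2-year pigs were spread widely. Pigs 9994, 9995 and 9997 had PC1 scores from 32.5 to 50.4, while pigs 9006 and 9007 had scores from 14.5 to 23.7. The mean of the lymphocyte markers was 6.74 to 7.62 in the arrays of pigs 9994, 9995 and 9997 and 5.88 to 6.07 in those of 9006 and 9007.

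**Figure D1:**
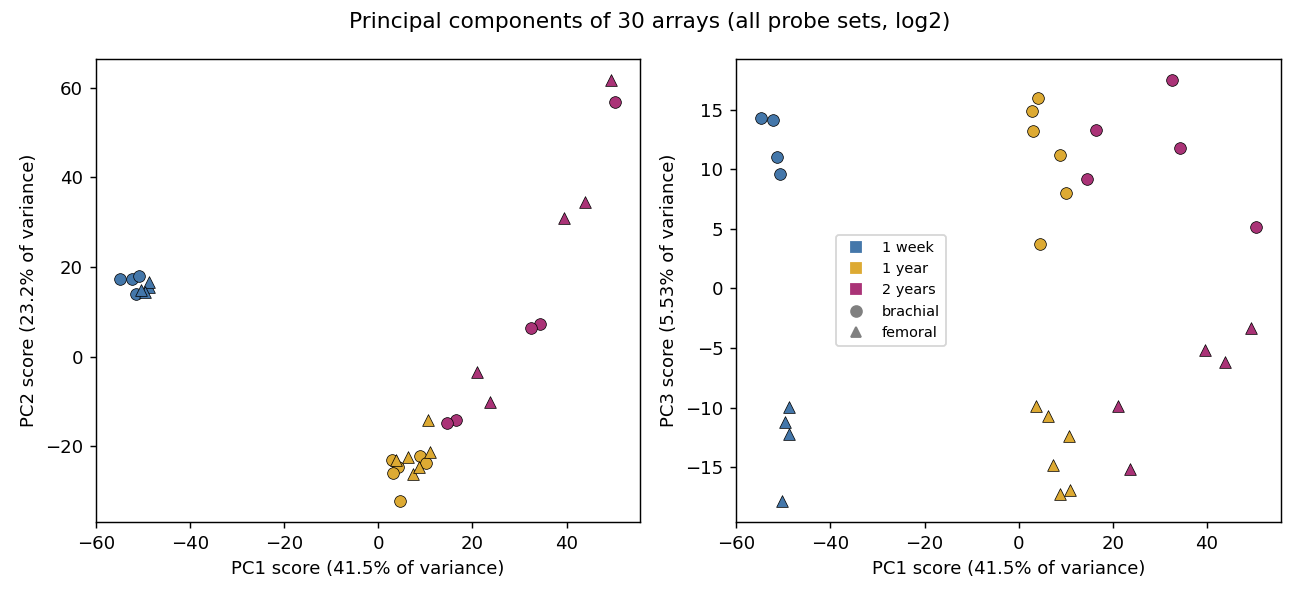
Principal component scores of the 30 arrays, with PC1 (41.5% of variance) on both horizontal axes and PC2 (23.2%) or PC3 (5.53%) on the vertical axes; colour gives age and shape gives the artery. The ages separate on PC1, the arteries on PC3, and the 2-year arrays spread along PC2.

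The first question was which genes differ between the brachial and the femoral artery. Among genes with a symbol, the largest increase in the femoral artery was that of COMP, a cartilage and tendon matrix protein (log2 fold change 1.39 ± 0.17, adjusted p = 1.24e-05, higher in 14 of 15 pigs). Increases in 15 of 15 pigs were found for GPRC5C, an orphan receptor (1.19 ± 0.12), MYO5B, a vesicle motor (1.16 ± 0.12), UBE2QL1 (1.10 ± 0.12), SEPT4, a septin (1.02 ± 0.11), and KCNB2, a potassium channel (0.83 ± 0.09). SMPDL3A, a phosphodiesterase (1.17 ± 0.29), RNF128, a ubiquitin ligase (1.11 ± 0.20), and GPNMB, a glycoprotein abundant in lipid-laden macrophages (0.94 ± 0.25), rose in 13 of 15 pigs, and CLDN11, a tight junction protein, in 12 (0.83 ± 0.19). Of the 4 probe sets of GPNMB 2 were called, with values from 0.11 to 0.94. The largest decrease of a gene with a symbol was that of RTN1, a reticulon of the endoplasmic reticulum (-2.14 ± 0.17, adjusted p = 1.23e-07, lower in 15 of 15 pigs).

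Other genes were lower in the femoral artery of all 15 pigs. They were GJA1, a gap junction protein (-1.92 ± 0.15), BDNF, a neurotrophin (-1.80 ± 0.21), KCNE1, a potassium channel subunit (-1.64 ± 0.19), ROPN1L (-1.29 ± 0.14), the cardiac actin ACTC1 (-1.23 ± 0.12) and the angiotensin receptor AGTR1 (-1.09 ± 0.09). TPPP3, a tubulin-binding protein (-1.58 ± 0.23), the formin FHOD3 (-1.07 ± 0.14) and ENPP2, the enzyme that makes lysophosphatidic acid (-1.06 ± 0.18), were lower in 14 of 15 pigs. Of 19362 probe sets, 2431 were called, 1272 higher and 1159 lower in the femoral artery, and 61 of them changed at least 2-fold. Among named genes 785 of 6054 were called. Without the pig as a block 1329 probe sets were called, and SMPDL3A (adjusted p = 0.187), RNF128 (0.053) and GPNMB (0.146) were no longer among them. With the pig as a random block SMPDL3A was not called (adjusted p = 0.0594), and with the title number as a covariate 1061 probe sets were.

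**Figure D2:**
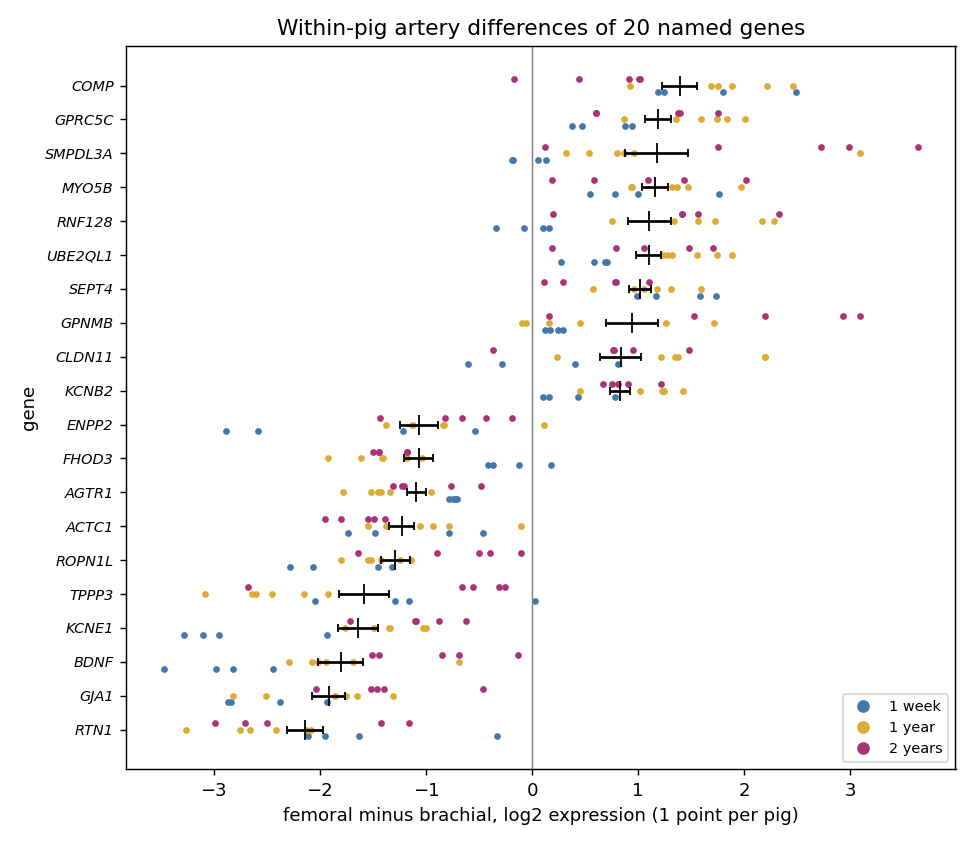
Femoral minus brachial log2 expression of the 20 genes named for the artery comparison, with a point for each of the 15 pigs coloured by age; the black marks are the fitted log2 fold change ± standard error. RTN1, GJA1 and BDNF lie below 0 in all 15 pigs, while SMPDL3A and GPNMB are highest at 2 years, with fitted values of 2.25 and 1.98.

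Some limb identity and patterning factors were higher in the femoral artery. Of 7 measured, 4 were called higher (5 adjusted over the list alone) and 0 lower: the homeobox genes MEIS2 (0.63 ± 0.07), MEIS1 (0.32 ± 0.06) and MSX1 (0.34 ± 0.07), and the T-box gene TBX2 (0.38 ± 0.06). The list test gave adjusted p = 0.000169, and adjusted p = 0.131 with an estimated correlation. Only 5 HOX genes were measured by a probe set of their own, so their lists were too short to test. HOXA3 was lower in the femoral artery of 14 of 15 pigs (-0.40 ± 0.07, adjusted p = 0.000406) and HOXD8 was higher in 15 of 15 (0.19 ± 0.04, adjusted p = 0.00623). HOXD8 was not called without the pig block (adjusted p = 0.285), with the pig as a random block (0.0859) or with the title number as a covariate (0.221). HOXA9 (-0.17 ± 0.06, adjusted p = 0.0921), HOXB7 (0.04 ± 0.05, adjusted p = 0.656) and HOXD10 (0.06 ± 0.04, adjusted p = 0.414) were not called. Without pig 9487 HOXA9 was called (adjusted p = 0.0441).

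The interferon, macrophage, lipid and cell cycle lists were called higher in the femoral artery. Of 21 interferon response genes 7 were called higher (10 adjusted over the list alone), among them USP18 (0.73 ± 0.09), IFIT3 (0.57 ± 0.11) and OAS1 (0.53 ± 0.12), with a list adjusted p = 0.00218, and adjusted p = 0.679 with an estimated correlation. Of 26 genes of lipid uptake and efflux 6 were called higher (11 adjusted over the list alone), with the cholesterol exporter ABCA1 (0.60 ± 0.11) and the lysosomal cholesterol carrier NPC2 (0.30 ± 0.07) among them (list adjusted p = 0.00224, and adjusted p = 0.679 with an estimated correlation). Of 16 macrophage and monocyte markers 5 were called higher (8 adjusted over the list alone), including SPI1 (0.46 ± 0.11) and ITGB2 (0.55 ± 0.14). Their adjusted p = 0.00657 became adjusted p = 0.715 with an estimated correlation, and the call also ended without pigs 9994, 9995 and 9997 (0.158), without the pig block (0.236), with the random block (0.188) and without the lowest 50% of probe sets (0.0768). Fry, which tests for a shift in a shared direction against no change, gave 0.128. Of 26 cell cycle genes 11 were called higher and 1 lower (15 and 1 adjusted over the list alone), such as CCNB1 (0.52 ± 0.11) and UBE2C (0.40 ± 0.09). The list adjusted p = 0.000985 became adjusted p = 0.679 with an estimated correlation. Without the lowest 50% of probe sets neither the cell cycle list (0.713) nor the interferon list (0.191) was called.

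Some adventitial and nerve markers were lower in the femoral artery. Of 16 adventitial fibroblast markers 5 were called lower and 1 higher (7 and 1 adjusted over the list alone), such as DPT, a matrix protein (-0.73 ± 0.21), and the transcription factor MEOX2 (-0.37 ± 0.08). For the list, adjusted p = 0.00224 became adjusted p = 0.679 with an estimated correlation, and fry gave 0.0551. Of 7 Schwann and nerve markers 3 were called lower (5 adjusted over the list alone), MAL (-0.36 ± 0.07), S100B (-0.21 ± 0.06) and GAP43 (-0.27 ± 0.09), with a list adjusted p = 0.00581, and adjusted p = 0.158 with an estimated correlation. Of 30 heat shock and chaperone genes 5 were called lower and 1 higher (7 and 1 adjusted over the list alone), the chaperones HSPA8 (-0.35 ± 0.08) and DNAJA1 (-0.32 ± 0.10) lower and HMOX1, heme oxygenase, higher (0.36 ± 0.10). The list adjusted p = 0.0227 became adjusted p = 0.679 with an estimated correlation, 0.0808 with the title number, 0.0592 without pig 9995, 0.172 without pigs 9994, 9995 and 9997, 0.143 with fry and 0.157 on every probe set.

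Few smooth muscle contractile genes differed. Of 22, 3 were called lower and 0 higher (4 lower and 1 higher adjusted over the list alone): the integrin ITGA8 (-0.88 ± 0.06), PDLIM3 (-1.02 ± 0.09) and the visceral actin ACTG2 (-0.36 ± 0.07). The list's test pointed down, as did its mean (-0.08), while its median was positive (0.02). Its adjusted p = 0.0375 became adjusted p = 0.828 with an estimated correlation, 0.0554 after quantile normalization and 0.0689 without the lowest 50% of probe sets. It was 0.312 without the pig block, 0.190 with the random block, 0.576 without pigs 9994, 9995 and 9997, and 0.334 with fry. Leaving out a single pig ended the call as well: 9007 (adjusted p = 0.0789), 9175 (0.0716), 9176 (0.0559), 9192 (0.0558), 9237 (0.0633), 9994 (0.147), 9995 (0.0923) or 9997 (0.0844). ACTA2, the main smooth muscle actin, did not differ detectably (-0.0042 ± 0.03, adjusted p = 0.953, and 0.02 after quantile normalization). Its mean of 14.73 lay near the highest signals of the arrays, which limits what they can show for it. Lists of endothelial (adjusted p = 0.524), lymphocyte (0.0991), erythroid and platelet blood (0.654), skeletal muscle (0.540) and adipocyte markers (0.788) were not called. NOS3, the endothelial nitric oxide synthase (-0.13 ± 0.12, adjusted p = 0.507), and APOB (0.02 ± 0.06, adjusted p = 0.861) were not called either. In all 9 of 32 lists were called, and 0 with an estimated correlation.

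The artery comparison was then made within each age. At 1 week (n = 4 pigs) the largest increases of named genes in the femoral artery were those of COMP (1.68 ± 0.23), PARM1 (1.45 ± 0.14), SEPT4 (1.37 ± 0.16) and EFHD1, a mitochondrial calcium-binding protein (1.36 ± 0.11). The largest decreases were those of LOC414400 (-3.10 ± 0.37), BDNF (-2.93 ± 0.23), KCNE1 (-2.82 ± 0.18) and GJA1 (-2.50 ± 0.23). LOC414400 has 2 probe sets, of which 1 was called and the other was at -0.20. Each of these 8 genes had the same direction in 4 of 4 pigs. Of 22 smooth muscle contractile genes 8 were called higher and 2 lower (12 and 2 adjusted over the list alone), with SYNM (0.87 ± 0.09), MYL9 (0.70 ± 0.10) and CSRP1 (0.67 ± 0.11) higher and ITGA8 lower (-0.83 ± 0.10). For the list, adjusted p = 9.28e-05 became adjusted p = 0.517 with an estimated correlation.

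Of 13 Wnt genes 4 were called lower at 1 week (5 adjusted over the list alone). They were the secreted inhibitors DKK1 (-2.39 ± 0.18), SFRP1 (-0.81 ± 0.08) and DKK3 (-0.48 ± 0.08) and the receptor FZD6 (-0.70 ± 0.14), with a list adjusted p = 9.28e-05, and adjusted p = 0.476 with an estimated correlation. Of 24 immediate early genes 4 were called lower and 1 higher (6 and 1 adjusted over the list alone), with SGK1 (-0.95 ± 0.16) and EGR1 (-0.91 ± 0.26) lower. The list adjusted p = 0.000666 became adjusted p = 0.517 with an estimated correlation, and fry gave 0.174. Of 23 collagen and matrix genes 6 were called lower and 1 higher (7 and 3 adjusted over the list alone), with POSTN (-1.44 ± 0.26) and VCAN (-1.14 ± 0.24) among the lower (list adjusted p = 0.015, and adjusted p = 0.517 with an estimated correlation). Their call ended without pig 9485 (0.154) and with the actin signal as a covariate (0.0648). Fry, which tests for a shift in a shared direction against no change, gave 0.174.

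Further lists were called at 1 week. Of 26 cell cycle genes 6 were called higher (9 adjusted over the list alone), PLK1 by 0.54 ± 0.10 and AURKB by 0.45 ± 0.08, with a list adjusted p = 0.000567, adjusted p = 0.517 with an estimated correlation, and 0.479 without the lowest 50% of probe sets. Of 16 adventitial fibroblast markers 4 were called lower (4 adjusted over the list alone), with DPT at -1.44 ± 0.27 and CLU at -0.63 ± 0.14 (list adjusted p = 0.000174, adjusted p = 0.517 with an estimated correlation, and 0.0954 with fry). Of 39 oxidative phosphorylation genes 3 were called higher (1 adjusted over the list alone), such as NDUFV1 (0.28 ± 0.07), with a list adjusted p = 0.00204, adjusted p = 0.745 with an estimated correlation, and 0.174 with fry. Of 7 Schwann and nerve markers 2 were called lower (2 adjusted over the list alone), GAP43 (-0.64 ± 0.13) and MBP (-0.72 ± 0.16). As a list, their adjusted p = 0.0416 became adjusted p = 0.517 with an estimated correlation, 0.0543 after quantile normalization, 0.123 without the pig block, 0.109 with the random block, 0.111 with the actin covariate and 0.0639 on every probe set. It was also not called without pig 9483 (0.0543), 9485 (0.068) or 9487 (0.123). At this age 1697 probe sets were called, 878 higher and 819 lower, against 525 without the pig block, 871 in a fit to this age alone and 805 without pig 9483.

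At 1 year (n = 6 pigs) SPP1, osteopontin, was the named gene with the largest increase in the femoral artery (2.31 ± 0.30), followed by COMP (1.82 ± 0.19), RNF128 (1.64 ± 0.20) and the nuclear receptor NR4A2 (1.61 ± 0.18). RTN1 (-2.55 ± 0.23), TPPP3 (-2.47 ± 0.26), GJA1 (-1.98 ± 0.19) and BDNF (-1.78 ± 0.19) were lowest, and all 8 genes had the same direction in 6 of 6 pigs. Of 24 immediate early genes 11 were called higher and 0 lower (14 higher and 2 lower adjusted over the list alone). CYR61 (1.15 ± 0.15), IER3 (1.02 ± 0.14) and DUSP1 (0.85 ± 0.17) were among them, with a list adjusted p = 4.29e-09, and adjusted p = 0.364 with an estimated correlation. Of 10 arterial Notch and flow-responsive genes 2 were called higher (5 higher and 1 lower adjusted over the list alone), HES1 (0.96 ± 0.13) and the connexin GJA5 (0.39 ± 0.10), with a list adjusted p = 0.00217, and adjusted p = 0.117 with an estimated correlation. Limb factors were higher with 3 of 7 called (6 adjusted over the list alone), MEIS2 by 0.75 ± 0.10, and a list adjusted p = 9.99e-06, or adjusted p = 0.0854 with an estimated correlation.

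A few smooth muscle, adventitial and nerve markers were lower in the femoral artery at 1 year. Of 22 smooth muscle contractile genes 3 were called lower (5 adjusted over the list alone), ITGA8 (-1.04 ± 0.08), PDLIM3 (-1.15 ± 0.15) and ACTG2 (-0.58 ± 0.08), with a list adjusted p = 0.00193, adjusted p = 0.636 with an estimated correlation, 0.104 with the title number and 0.0709 with fry. Of 16 adventitial fibroblast markers 3 were called lower (5 adjusted over the list alone), DPT (-1.11 ± 0.22), MEOX2 (-0.52 ± 0.12) and MFAP5 (-0.43 ± 0.11), with a list adjusted p = 0.000744, adjusted p = 0.636 with an estimated correlation, and 0.0795 with fry. Of 7 Schwann and nerve markers 2 were called lower (3 adjusted over the list alone), MAL (-0.50 ± 0.09) and NCAM1 (-0.49 ± 0.11), with a list adjusted p = 0.000796, and adjusted p = 0.0854 with an estimated correlation. Of 21 interferon response genes 4 were called higher (6 adjusted over the list alone), ISG15 by 1.21 ± 0.17 and RSAD2 by 0.69 ± 0.15. Their adjusted p = 0.00904 became adjusted p = 0.657 with an estimated correlation, 0.357 without the lowest 50% of probe sets and 0.185 with fry.

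Metabolic lists at 1 year were less certain. Of 26 lipid uptake and efflux genes 2 were called higher (5 adjusted over the list alone), PON2 (0.35 ± 0.06) and ABCA1 (0.68 ± 0.14). As a list, their adjusted p = 0.018 became adjusted p = 0.636 with an estimated correlation, 0.118 without the pig block, 0.0767 with the random block, 0.0814 with the title number, 0.0523 without pig 9175 and 0.185 with fry. Of 18 glycolysis genes 3 were called lower (5 adjusted over the list alone), ALDOC (-0.40 ± 0.07), ENO3 (-0.41 ± 0.09) and the glucose transporter SLC2A1 (-0.29 ± 0.08). Their adjusted p = 0.0307 became adjusted p = 0.636 with an estimated correlation, 0.0889 without the block, 0.0744 with the random block, 0.0501 without the lowest 50% of probe sets, 0.0523 without pig 9175, 0.0742 without pig 9188, 0.115 with fry and 0.0548 on every probe set. In all, 1357 probe sets were called, 661 higher and 696 lower, and 439 without the pig block. RNF128 was not called without the block (adjusted p = 0.145).

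At 2 years (n = 5 pigs) the named genes with the largest increases in the femoral artery were SMPDL3A (2.25 ± 0.38), ACP5, an acid phosphatase (1.98 ± 0.32), GPNMB (1.98 ± 0.31) and the chemokine CXCL14 (1.86 ± 0.33). RTN1 (-2.16 ± 0.26), ACTC1 (-1.63 ± 0.18), GJA1 (-1.37 ± 0.20) and FHOD3 (-1.35 ± 0.11) were lowest. These genes had the same direction in 5 of 5 pigs, except ACP5, which was higher in 4. Of the 4 probe sets of GPNMB 3 were called here, with values from 0.25 to 1.98. Of 16 macrophage and monocyte markers 11 were called higher and 0 lower (15 higher adjusted over the list alone), with TYROBP (1.15 ± 0.16), FCER1G (1.34 ± 0.19) and ITGB2 (1.12 ± 0.19) among them. The list median was 0.77, with adjusted p = 2.14e-14, and adjusted p = 0.335 with an estimated correlation. Of 26 lipid uptake and efflux genes 11 were called higher (15 adjusted over the list alone), such as APOE (1.74 ± 0.33), the lysosomal lipase LIPA (1.20 ± 0.21), ABCA1 (0.88 ± 0.15) and NPC1 (0.62 ± 0.12), with a list adjusted p = 2.79e-07, and adjusted p = 0.335 with an estimated correlation.

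Some lymphocyte, smooth muscle and interferon genes differed at 2 years too. Of 12 lymphocyte markers 3 were called lower in the femoral artery (8 adjusted over the list alone), CD247 (-0.50 ± 0.12), JCHAIN (-0.54 ± 0.14) and IL7R (-0.44 ± 0.13), with a list adjusted p = 7.97e-06, and adjusted p = 0.335 with an estimated correlation. Of 22 smooth muscle contractile genes 4 were called lower (6 adjusted over the list alone), ITGA8 (-0.73 ± 0.09), PDLIM3 (-0.97 ± 0.16), ACTG2 (-0.37 ± 0.08) and PLN (-0.55 ± 0.12), with a list adjusted p = 1.62e-06, and adjusted p = 0.335 with an estimated correlation. Without pigs 9994, 9995 and 9997 the lymphocyte list (0.616) and the smooth muscle list (0.0777) were no longer called in femoral against brachial at 2 years. Of 21 interferon response genes 8 were called higher (11 higher and 1 lower adjusted over the list alone), with ISG15 at 1.02 ± 0.18 and a list adjusted p = 8.13e-05, or adjusted p = 0.511 with an estimated correlation. That call ended without the lowest 50% of probe sets (0.0815).

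Other lists called at 2 years depended more on the settings. Of 30 heat shock and chaperone genes 1 was called higher, HMOX1 (0.63 ± 0.15), and 1 lower, HSPB7 (-0.38 ± 0.08), with the same counts adjusted over the list alone. For the list, adjusted p = 0.00176 became adjusted p = 0.415 with an estimated correlation, 0.0642 without pigs 9994, 9995 and 9997, and 0.0787 with fry. Of 7 limb factors 2 were called higher (4 adjusted over the list alone), MEIS1 (0.53 ± 0.09) and MEIS2 (0.59 ± 0.11), with a list adjusted p = 0.026, and adjusted p = 0.335 with an estimated correlation. It was not called without pig 9006 (0.133), 9007 (0.0707) or 9997 (0.0579), without the block (0.092), with the random block (0.069) or without the lowest 25% of probe sets (0.0654). Of 11 MHC class II genes 3 were called higher (3 adjusted over the list alone), among them SLA-DMB (0.56 ± 0.12), with a list adjusted p = 0.0229, and adjusted p = 0.514 with an estimated correlation. That call ended without pig 9007 (0.0933) or 9994 (0.0753), without the block (0.248) and with the random block (0.217). Fry, which tests for a shift in a shared direction against no change, gave 0.0731.

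The sterol and adipocyte lists were also called at 2 years. Of 14 sterol synthesis genes 3 were called lower (3 adjusted over the list alone), SC5D (-0.44 ± 0.09), CYP51 (-0.39 ± 0.08) and FDPS (-0.40 ± 0.10), with a list adjusted p = 0.0255, and adjusted p = 0.512 with an estimated correlation. The call ended without pig 9994 (0.167) or 9997 (0.116), without pigs 9994, 9995 and 9997 (0.581), without the block (0.175), with the random block (0.135) and on every probe set (0.137). Fry, which tests for a shift in a shared direction against no change, gave 0.124. Of 14 adipocyte markers 3 were called higher (6 adjusted over the list alone), SCD (1.26 ± 0.18), LPL (1.58 ± 0.33) and FASN (0.24 ± 0.07). As a list, their adjusted p = 0.048 became adjusted p = 0.512 with an estimated correlation, and most settings ended it, among them the fit to this age alone (0.173), the removal of pig 9994 (0.167) or 9995 (0.0571), and of the 3 pigs together (0.202). Of 26 cell cycle genes 0 were called by limma at 2 years (0 adjusted over the list alone), with STMN1 at -0.27 ± 0.08 and MCM4 at 0.30 ± 0.10, though the list was (adjusted p = 0.0331, and adjusted p = 0.556 with an estimated correlation). It was not without the lowest 50% of probe sets (0.931), pig 9994 (0.0753), pig 9995 (0.228) or the 3 pigs (0.733).

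There were 1545 probe sets called, 867 higher and 678 lower. The count was 100 without the pig block, where SMPDL3A (0.333), ACP5 (0.306), GPNMB (0.220) and CXCL14 (0.268) were not called, 677 with the random block, and 658 in a fit to this age alone. It was 920 without pig 9994, 724 without pig 9995 and 524 without 9994, 9995 and 9997 together.

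Genes fixed by name gave few calls within an age. HOXA3 was lower in the femoral artery at 1 year (-0.52 ± 0.09, adjusted p = 0.00191) and at 2 years (-0.46 ± 0.10, adjusted p = 0.0103), but was not called at 1 week (-0.16 ± 0.12, adjusted p = 0.471). The call at 2 years ended without pig 9994 (0.0575) or 9995 (0.0663), without both and pig 9997 (0.438) and without the pig block (0.204). HOXD8 at 1 week (0.28 ± 0.09, adjusted p = 0.0521) was called without pig 9483 (0.0312) or 9487 (0.0389). With every pig kept it was called after quantile normalization (0.0411) or a median shift (0.045), without the lowest 25% (0.0404) or 50% (0.0314) of probe sets, with an intensity trend (0.0449) and with array weights (0.0229). NOS3 at 1 week (-0.52 ± 0.20, adjusted p = 0.118) was called with the title number as a covariate (-0.95, adjusted p = 0.0114) and without pig 9481 (0.00598). Without that pig so was its test of artery by age (0.0299, against 0.267 with every pig). HOXA9 at 2 years (-0.27 ± 0.11, adjusted p = 0.145) was called without pig 9006 (0.0407).

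A further test asked whether the artery effect depended on age. The 1-week pigs also differed from the older pigs in RNA isolation, and the sex of the pigs is not in the labels. Differences between 1 week and the later ages cannot be told apart from these. DKK1, a Wnt inhibitor, had the smallest p (adjusted p = 0.000174), and was lower in the femoral artery at 1 week (-2.39 ± 0.18) but -0.29 ± 0.15 at 1 year and -0.13 ± 0.16 at 2 years, where it was not called. EFHD1 (1.36 ± 0.11 at 1 week) and the tight junction gene CLDN10 (1.26 ± 0.13 at 1 week) were not called at the later ages, nor was SFRP1 (-0.81 ± 0.08 at 1 week). FHOD3 was -0.18 ± 0.12 at 1 week, where it was not called, -1.43 ± 0.10 at 1 year and -1.35 ± 0.11 at 2 years. ENO3, a muscle enolase, was called higher in the femoral artery at 1 week (0.61 ± 0.11) and lower at 1 year (-0.41 ± 0.09) and 2 years (-0.53 ± 0.10). The leukotriene receptor CYSLTR2 (-1.40 ± 0.12) and LOC100621607 (-1.96 ± 0.17) were lower at 1 week and less so at 1 year (-0.74 ± 0.10 and -0.79 ± 0.14).

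The count for artery by age was 787 probe sets. Between pairs of ages, the artery effect differed at 275 probe sets for 1 year against 1 week and at 1154 for 2 years against 1 week. By limma 0 differed between 2 years and 1 year, with 2397 at an unadjusted p under 0.05. Without the pig block the count for artery by age was 12, where DKK1 remained called and EFHD1 (adjusted p = 0.0538), CLDN10 (0.478), FHOD3 (0.175), CYSLTR2 (0.306), ENO3 (0.158), LOC100621607 (0.142) and SFRP1 (0.151) did not. The count was 411 with the random block, 292 without pig 9483, 487 without 9485, 436 without 9487, 457 without 9994, 410 without 9995, and 241 without 9994, 9995 and 9997. Probe sets called at 1 week and at 1 year numbered 514, of which 504 had the same direction, where independent lists would share 119. For 1 week and 2 years it was 294, with 250 in the same direction and 135 for independent lists, and for 1 year and 2 years 469, 465 and 108. The artery effects were fitted with a shared spread for each probe set, so calls at 2 ages are not independent. The counts for independent lists may therefore be too low as a baseline.

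Camera on all 32 lists called 9 for the artery effect at 1 year minus 1 week, 15 for 2 years minus 1 week and 14 for 2 years minus 1 year. With an estimated correlation 0 of these stayed called, and with fry 3, 2 and 0 were. Means of a list per pig gave exact tests of the same question for 5 lists, chosen after seeing the data. The adjustment covers only their 15 tests. The mean of the smooth muscle contractile genes was higher in the femoral artery of 4 of 4 pigs at 1 week (by 0.22), and lower there in 6 of 6 pigs at 1 year (-0.15) and 5 of 5 at 2 years (-0.21). The effects at 1 year and at 1 week differed by -0.37 (exact permutation p = 0.00476, adjusted p = 0.0476 over 15 tests). The immediate early mean had an artery difference of -0.35 at 1 week, with the femoral artery higher in 1 of 4 pigs, 0.43 at 1 year (5 of 6 pigs) and 0.19 at 2 years (5 of 5). The gap between 1 year and 1 week was 0.78 (exact permutation p = 0.00952, adjusted p = 0.0476). The macrophage mean was higher in the femoral artery by 0.75 in 5 of 5 pigs at 2 years and by 0.07 at 1 year, a gap of 0.67 that did not pass (exact permutation p = 0.0303, adjusted p = 0.0649). The lymphocyte mean had an artery difference of -0.35 at 2 years, with the femoral artery higher in 1 of 5 pigs, and 0.02 at 1 year. That gap of -0.37 passed (exact permutation p = 0.0152, adjusted p = 0.0476), while the gap of -0.38 between 2 years and 1 week did not (exact permutation p = 0.119, adjusted p = 0.165). The lipid uptake and efflux mean was higher in the femoral artery of 5 of 5 pigs at 2 years (0.46) and 6 of 6 at 1 year (0.16), and its gaps between ages did not pass (adjusted p = 0.0649 for 1 year against 1 week, 0.0926 for 2 years against 1 week and 0.165 for 2 years against 1 year).

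**Figure D3:**
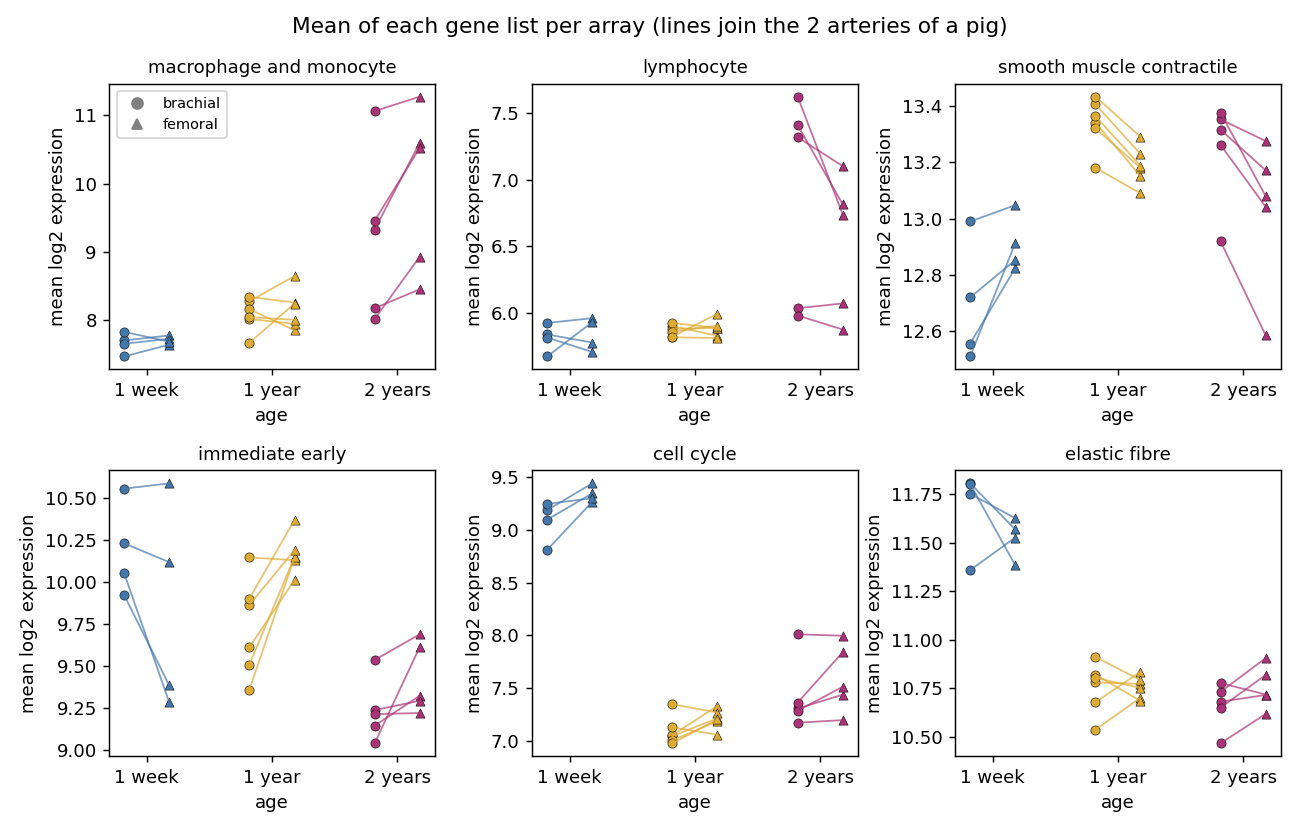
Mean log2 expression of 6 gene lists in each array, by age, with circles for brachial and triangles for femoral arteries and lines joining the arteries of a pig. The smooth muscle mean is higher in the femoral artery in 4 of 4 pigs at 1 week and lower in 6 of 6 at 1 year, and the macrophage and lymphocyte means are widely spread at 2 years.

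Ages were compared next, beginning with 1 year against 1 week. Cell division genes were the most reduced named genes: CCNB1 (-4.54 ± 0.26), CKS2 (-4.12 ± 0.29), TOP2A (-3.95 ± 0.24), CENPF (-3.52 ± 0.18), PCLAF (-3.49 ± 0.29), CCNB2 (-3.46 ± 0.17), DLGAP5 (-3.34 ± 0.18), UBE2C (-3.28 ± 0.21), HMMR (-3.14 ± 0.22) and CEP55 (-3.13 ± 0.13), with n = 6 against 4 pigs. Of 26 cell cycle genes 23 were called lower and 0 higher (23 lower adjusted over the list alone), with a median of -2.01, adjusted p = 1.08e-40, and adjusted p = 0.247 with an estimated correlation. Of 9 elastic fibre genes 7 were called lower (8 adjusted over the list alone), such as FBN1, fibrillin (-1.38 ± 0.07), MFAP2 (-1.31 ± 0.12) and the crosslinking enzyme LOXL1 (-1.01 ± 0.08), with a list adjusted p = 3.58e-06, and adjusted p = 0.175 with an estimated correlation. Of 23 collagen and matrix genes 17 were called lower and 2 higher (18 and 2 adjusted over the list alone), with COL1A2 at -1.48 ± 0.15 and COL5A1 at -1.23 ± 0.08 (list adjusted p = 0.000161, and adjusted p = 0.175 with an estimated correlation).

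Antigen presentation genes were among the largest increases of named genes at 1 year against 1 week. SLA-DRA (3.48 ± 0.41), the invariant chain CD74 (3.04 ± 0.40) and SLA-DRB1 (2.80 ± 0.38) rose, and of 11 MHC class II genes 8 were called higher (9 adjusted over the list alone), with a list adjusted p = 0.00933, and adjusted p = 0.950 with an estimated correlation. Of 21 interferon response genes 16 were called higher (16 adjusted over the list alone), such as ISG15 (1.86 ± 0.29) and DDX58 (1.55 ± 0.15), with a list adjusted p = 0.00425, and adjusted p = 0.950 with an estimated correlation. GBP1, a GTPase induced by interferon, rose by 2.45 ± 0.70, but only 1 of its 3 probe sets was called (lowest value 0.71). Of 17 complement genes 9 were called higher (10 adjusted over the list alone), with CFD at 1.63 ± 0.18 and C1S at 1.09 ± 0.11, and the list adjusted p = 0.00811 became adjusted p = 0.950 with an estimated correlation. C3, the central complement protein, rose by 2.55 ± 0.43. Moving with these genes, the mean of the macrophage markers rose by 0.44 and that of the adventitial fibroblast markers by 0.48, while the 18S rRNA signal fell by 0.44 (exact permutation p = 0.00476 and adjusted p = 0.019 for each). Of 22 smooth muscle contractile genes 13 were called higher and 1 lower (14 and 1 adjusted over the list alone), SYNM by 1.60 ± 0.12, CSRP1 by 1.31 ± 0.11 and DES, desmin, by 1.24 ± 0.17. Their adjusted p = 0.00811 became adjusted p = 0.967 with an estimated correlation and 0.140 with femoral arrays only.

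The named gene with the largest increase at 1 year against 1 week was EIF1AY, a translation factor gene that is Y-linked in mammals (5.37 ± 0.14, adjusted p = 2.93e-13). Its mean was 3.75 ± 0.29 (SD, n = 4 pigs) at 1 week, 9.12 ± 0.21 (n = 6) at 1 year and 9.17 ± 0.18 (n = 5) at 2 years. KCNE1 (2.97 ± 0.26), LOC106504372 (2.66 ± 0.35), KIAA1644 (2.64 ± 0.33) and MYOC, myocilin (2.59 ± 0.27), rose as well. In all, 8692 of 19362 probe sets were called, 4773 higher and 3919 lower, and 885 of them changed at least 2-fold. Without the lowest 50% of probe sets, which also tests fewer, 5353 were called. The RNA of the piglets was isolated by another method than that of the older pigs, so age and isolation cannot be told apart in this comparison or in the next. The sex of the pigs is not in the labels, so a difference in sex between piglets and older pigs cannot be told apart from these either.

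At 2 years against 1 week (n = 5 against 4 pigs) EIF1AY (5.41 ± 0.14), LOC396781 (4.88 ± 1.30), SLA-DRA (4.59 ± 0.42) and CD74 (4.34 ± 0.41) rose most among named genes. CCNB1 (-3.87 ± 0.27), the growth factor PTN (-3.66 ± 0.27), the transcription factor FOS (-3.64 ± 0.68) and CCDC30 (-3.47 ± 0.51) fell most. All of the 11 MHC class II genes were called higher (11 adjusted over the list alone, median 2.93), with a list adjusted p = 2.09e-05, and adjusted p = 0.549 with an estimated correlation. Of 17 complement genes 14 were called higher (14 adjusted over the list alone), C3 by 4.28 ± 0.44, with the same adjusted p = 2.09e-05, and adjusted p = 0.549 with an estimated correlation. Of 16 macrophage and monocyte markers 13 were called higher (14 adjusted over the list alone), FCER1G by 3.49 ± 0.56, with a list adjusted p = 0.0142, adjusted p = 0.676 with an estimated correlation, and 0.0503 without the lowest 50% of probe sets. Without pigs 9994, 9995 and 9997 these lists stayed called, but their medians shrank from 2.93 to 1.51 for MHC class II genes (10 of 11 called), from 1.11 to 0.81 for complement genes (11 of 17) and from 2.21 to 0.78 for macrophage markers (10 higher and 2 lower). Of 26 cell cycle genes 22 were called lower and 1 higher (23 and 1 adjusted over the list alone), CDC20 by -2.60 ± 0.11, with a list adjusted p = 5.81e-26, and adjusted p = 0.430 with an estimated correlation. Of 9 elastic fibre genes 7 were called lower (8 adjusted over the list alone), LOX by -1.55 ± 0.17, with a list adjusted p = 7.33e-06, and adjusted p = 0.194 with an estimated correlation.

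Of 21 interferon response genes 18 were called higher at 2 years against 1 week (18 adjusted over the list alone), such as ISG15 (2.39 ± 0.30) and PSMB8 (2.28 ± 0.28), with a list adjusted p = 0.000155, and adjusted p = 0.549 with an estimated correlation. Of 23 collagen and matrix genes 14 were called lower and 1 higher (14 and 2 adjusted over the list alone), COL1A2 by -2.24 ± 0.15 and COL5A1 by -1.56 ± 0.09, with a list adjusted p = 7.72e-06, and adjusted p = 0.188 with an estimated correlation. Of 39 oxidative phosphorylation genes 23 were called higher and 3 lower (23 and 4 adjusted over the list alone), with NDUFB10 at 0.72 ± 0.05 and COX5B at 0.62 ± 0.06. As a list, their adjusted p = 0.00654 became adjusted p = 0.676 with an estimated correlation, 0.145 with femoral arrays only and 0.618 with the actin covariate. Means of cell type markers rose in the same comparison, by 0.67 for endothelial, 0.58 for adventitial fibroblast and 0.35 for skeletal muscle markers (exact permutation p = 0.00794 and adjusted p = 0.0224 for each).

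The count at 2 years against 1 week was 9674 probe sets, 4675 higher and 4999 lower. It was 5566 without the lowest 50% of probe sets and 2906 with the beta actin 3' minus 5' signal as a covariate, where CCNB1 (-2.17, adjusted p = 0.0532) and CCDC30 (-3.22, 0.192) were not called. That signal was higher at 2 years than at 1 week by 0.38 (exact permutation p = 0.00794, adjusted p = 0.0224). Without pigs 9994, 9995 and 9997 the value of LOC396781 was 0.88 (adjusted p = 0.110).

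The comparison of 2 years against 1 year (n = 5 against 6 pigs) used RNA from a shared isolation method. The number in front of the titles was 748 to 762 at 1 year and 763 to 772 at 2 years. Age and anything that follows that number therefore cannot be told apart here. The largest increases of named genes included those of SMPDL3A (3.16 ± 0.75), SPP1 (2.92 ± 0.59), CHI3L1, a secreted chitinase-like protein (2.72 ± 0.60), RNF128 (2.69 ± 0.53), the leukocyte actin-bundling protein LCP1 (2.57 ± 0.61), APOE (2.56 ± 0.47) and ACP5 (2.54 ± 0.64). LOC396781 (4.46 ± 1.17), LOC100152327 (3.75 ± 0.89) and the interferon-induced chemokine CXCL9 (3.30 ± 0.97) rose too. Of the 5 probe sets of LCP1 4 were called, with values from 0.21 to 2.57. Of 16 macrophage and monocyte markers 13 were called higher and 0 lower (15 higher adjusted over the list alone), TYROBP by 2.25 ± 0.48, FCER1G by 2.31 ± 0.50 and AIF1 by 1.95 ± 0.45. The list median was 1.66, with adjusted p = 0.000483, and adjusted p = 0.526 with an estimated correlation. The beta actin 3' minus 5' signal moved with these genes, from 0.48 at 1 year to 0.81 at 2 years (exact permutation p = 0.00216, adjusted p = 0.0189), while that of GAPDH fell from 1.10 to 0.88 (p = 0.00433, adjusted p = 0.019).

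Of 12 lymphocyte markers 12 were called higher at 2 years against 1 year (12 adjusted over the list alone), CD3E by 1.38 ± 0.36, JCHAIN by 1.62 ± 0.43 and CD4 by 0.64 ± 0.16, with a list adjusted p = 0.00155, and adjusted p = 0.526 with an estimated correlation. Of 11 MHC class II genes 8 were called higher (10 adjusted over the list alone), CTSS by 2.43 ± 0.48, with a list adjusted p = 0.00772, and adjusted p = 0.526 with an estimated correlation. Of 17 complement genes 10 were called higher (10 adjusted over the list alone), C3 by 1.72 ± 0.40 and C4A by 1.25 ± 0.28, with a list adjusted p = 0.00883, and adjusted p = 0.526 with an estimated correlation. Of 26 cell cycle genes 14 were called higher (15 adjusted over the list alone), CKS2 by 1.06 ± 0.27, with a list adjusted p = 0.00772, and adjusted p = 0.593 with an estimated correlation. Without pigs 9994, 9995 and 9997 these 4 lists were no longer called: adjusted p = 0.573 for lymphocyte, 0.984 for MHC class II, and 0.438 for complement and for cell cycle genes. The complement call also ended with brachial arrays only (0.0596), and that of the cell cycle without pig 9997 (0.0552) or without the lowest 50% of probe sets (0.178). The macrophage list had a median of 0.27 without the 3 pigs (adjusted p = 0.0439), with 4 of 16 markers called.

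Most respiratory chain genes rose at 2 years against 1 year. Of 39 oxidative phosphorylation genes 29 were called higher and 0 lower (30 higher and 1 lower adjusted over the list alone), NDUFB10 by 0.48 ± 0.05, NDUFA2 by 0.73 ± 0.07 and ATP5G1 by 0.65 ± 0.07. The list adjusted p = 3.73e-14 became adjusted p = 0.526 with an estimated correlation and 0.057 with the actin signal as a covariate, where the list median shrank from 0.33 to 0.13 and 3 of 39 genes were called. Of 28 antioxidant genes 17 were called higher and 1 lower (18 and 1 adjusted over the list alone), GPX4 by 0.53 ± 0.08 and TXN, thioredoxin, by 0.42 ± 0.07, with a list adjusted p = 0.000483, and adjusted p = 0.526 with an estimated correlation. Of 26 lipid uptake and efflux genes 13 were called higher and 1 lower (19 and 1 adjusted over the list alone), ABCA1 by 1.79 ± 0.37 and FABP5 by 1.77 ± 0.38, with a list adjusted p = 0.00241, and adjusted p = 0.526 with an estimated correlation. Of 16 endothelial markers 9 were called higher (12 adjusted over the list alone), CDH5 by 0.67 ± 0.18. Their adjusted p = 0.00883 became adjusted p = 0.526 with an estimated correlation, 0.0673 with the actin covariate and 0.157 without the lowest 50% of probe sets. Without pigs 9994, 9995 and 9997 the antioxidant list had 12 of 28 genes called higher, the lipid list 6 of 26 (median 0.16 instead of 0.63, adjusted p = 0.0389) and the endothelial list 2 of 16 (median 0.31 instead of 0.39, adjusted p = 0.0439).

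The most reduced named genes at 2 years against 1 year included genes of the immediate early response. FOS (-4.05 ± 0.61), EGR1 (-2.35 ± 0.38), CYR61 (-1.74 ± 0.27), the phosphatase DUSP1 (-1.63 ± 0.21), PTGS2, a cyclooxygenase (-1.54 ± 0.33), NR4A2 (-1.53 ± 0.31), NFIL3 (-1.48 ± 0.22) and BTG2 (-1.36 ± 0.32) fell. So did the fuel-switching genes PDK4 (-1.41 ± 0.39) and CPT1B (-1.24 ± 0.17). Of 24 immediate early genes 10 were called lower and 3 higher (10 and 3 adjusted over the list alone), with a list adjusted p = 0.00386, and adjusted p = 0.526 with an estimated correlation. With the actin signal as a covariate the list (0.375) and DUSP1 (0.147), PTGS2 (0.204), NR4A2 (0.25), NFIL3 (0.430), PDK4 (0.185) and BTG2 (0.402) were not called. The list median shrank to -0.04, but the log2 fold changes of most of these genes did not shrink to match (DUSP1 -1.45, PTGS2 -1.95, NR4A2 -1.66, NFIL3 -0.80, PDK4 -2.38 and BTG2 -1.28). Their standard errors grew, to 0.647 for DUSP1 and 1.18 for PDK4, so the lost calls do not show that RNA integrity accounts for the decrease. Array weights ended the call of PDK4 (0.0563).

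In total 6329 probe sets were called at 2 years against 1 year, 2503 higher and 3826 lower, and of those that changed at least 2-fold 328 were higher and 66 lower. The count was 4118 without the lowest 50% of probe sets, 3953 with brachial arrays only, 3217 without pigs 9994, 9995 and 9997, and 1873 with the actin covariate. Without those 3 pigs LOC396781 (0.47, adjusted p = 0.470), LOC100152327 (0.71, 0.102), SPP1 (1.18, 0.0589), PTGS2 (-1.41, 0.063), NR4A2 (-1.13, 0.0836), PDK4 (-1.13, 0.148) and BTG2 (-0.97, 0.155) were not called, and CXCL9 was at -0.075 (0.689). CXCL9 was also not called without pig 9994 (0.0522) or 9995 (0.0501), and LOC396781 (0.050) and ACP5 (0.090) were not with brachial arrays only.

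**Figure D4:**
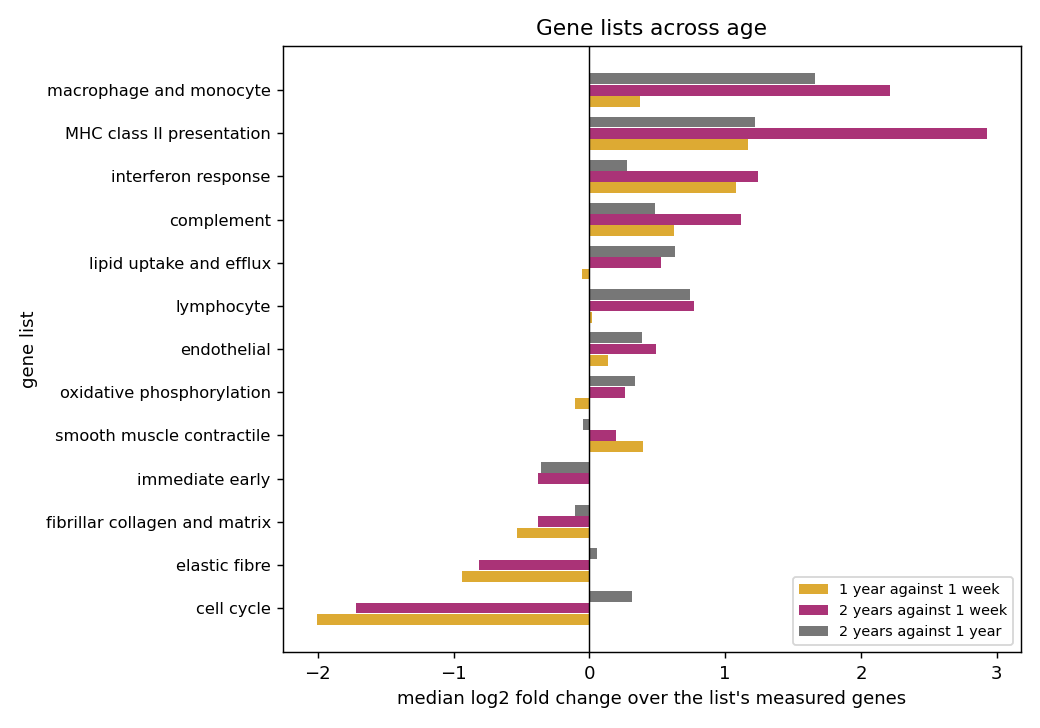
Median log2 fold change of 13 gene lists in the 3 age comparisons, as bars from 0 over the measured genes of each list. Cell cycle genes are lowest at 1 year against 1 week (-2.01), and macrophage genes rise by 1.66 at 2 years against 1 year, or by 0.27 without pigs 9994, 9995 and 9997.

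Genes fixed by name gave few calls with age. NOS3 was higher at 1 year against 1 week (0.85 ± 0.26, adjusted p = 0.0154) and at 2 years against 1 week (1.15 ± 0.27, adjusted p = 0.00264), but not at 2 years against 1 year (0.30 ± 0.25, adjusted p = 0.377). The call at 1 year ended without pig 9487 (0.0653) and with brachial arrays only (0.133), and that at 2 years with the actin covariate (0.4), where the log2 fold change stayed at 1.12 and the standard error grew to 0.863. HOXB7 was higher at 1 year (0.40 ± 0.09) and 2 years (0.52 ± 0.09) than at 1 week, and HOXD10 at 2 years (0.29 ± 0.09). With the actin covariate neither was called at 2 years against 1 week. HOXB7 stayed at 0.44 with a larger standard error of 0.279 (adjusted p = 0.302), while HOXD10 shrank to 0.06 (0.906). HOXA3 was not called at 1 year against 1 week (0.30 ± 0.12, adjusted p = 0.0649), but was with array weights (0.0114), the random block (0.0463), brachial arrays only (0.0186) and the compared ages alone (0.00536). It was lower at 2 years than at 1 year (-0.35 ± 0.12, adjusted p = 0.0301). Its call ended without pig 9176 (0.0629), 9188 (0.0508), 9994 (0.0705) or 9997 (0.064), in each artery alone (0.0605 and 0.0826), with the compared ages alone (0.0507), with the actin covariate (-0.66 with a standard error of 0.346, adjusted p = 0.212) and without pigs 9994, 9995 and 9997 (-0.13, 0.461). ACTA2, with a mean of 14.73 near the highest signals (adjusted p = 0.907, 0.448 and 0.534), and APOB, with a mean of 3.84 near the lowest signals (0.525, 0.461 and 0.941), were not called in any of the 3 age comparisons.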

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

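The patterns below were chosen after the data were seen. The test of RNA isolation for EIF1AY was chosen after its result was seen. The other tests of explanations, and the counts over other splits of the samples, were set before their results were seen.

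The gene EIF1AY was at 3.75 ± 0.29 (SD, n = 4 pigs) at 1 week, near the lowest signals of the arrays, and at 9.12 ± 0.21 (n = 6) at 1 year and 9.17 ± 0.18 (n = 5) at 2 years. A candidate explanation is that the piglets were female and the older pigs male, which the labels do not give. Under it, 7 X-linked genes that escape inactivation were to be lower in the older pigs, but their median log2 fold change of -0.08 lay at the 21.3 percentile of random lists, which decides neither way: 4 of the 7 were lower, MED14, TXLNG and SYAP1 among them called, while KDM5C and ZFX were called higher. KDM6A, seen before the test, fell by 0.71 ± 0.08, and SRY was not called (-0.10 ± 0.07). Sex, age and RNA isolation cannot be told apart here. EIF1AY differed by only 0.0488 between 2 years and 1 year, which share a method, and each of the 3 could give that value.

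Macrophage genes were higher at 2 years than at 1 year, with a list median of 1.66 over 16 markers, of which 2, C1QA and C1QC, also stand in the complement list. Residual blood is argued against by HBB, an abundant blood transcript at a mean of 9.53, whose log2 fold change was -0.0561 (95% interval -0.29 to 0.18). With the actin 3' minus 5' signal as a covariate the median was 4.97 and the list stayed called with 15 of 16 markers. The signal nearly follows age, with pig means of 0.81 ± 0.07 (SD) at 2 years and 0.48 ± 0.03 at 1 year. Standard errors grew 2.94 times and the size of that median is not reliable. The covariate therefore cannot decide whether RNA integrity contributes. Fat on the older arteries may contribute and stays open, since ADIPOQ gave -0.10 (95% interval -0.27 to 0.07) but lay at a mean of 5.28, below the lower quartile of 6.57, and the adipocyte list, with 7 of 14 markers called higher, had adjusted p = 0.124, while the mean of its markers rose by 0.57 (exact permutation p = 0.00216, adjusted p = 0.0189). Age, which the design names, and differences between the individual pigs stay open too. So does anything that follows the title numbers, which do not overlap between the 1-year and 2-year arrays. The list median was 0.27 without pigs 9994, 9995 and 9997. Those pigs had higher macrophage means (9.33 to 11.27 per array) than pigs 9006 and 9007 (8.02 to 8.93), the only 2-year pigs left. Leaving them out thus lowers the median by construction.

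Immediate early genes were lower in the femoral artery at 1 week and higher there at 1 year, with list medians of -0.22 and 0.41 and a gap of 0.638. With the actin 3' minus 5' signal as a covariate the gap was 0.569, and with the title number as a covariate it was 0.6, so neither may be the whole cause. The gap is in line with a difference between the ages, but the piglets' RNA isolation and the handling of each artery after death were not tested.

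Among the pig means and artery differences of named genes, 8 of 180 groups had a pig far from the others, measured as its gap to the nearest pig over the range of the group. That is 4.44%, and chance gives about 1 in 20. At 1 week pig 9487 stood high for EIF1AY (0.882 of the range), pig 9481 low for C3 (0.871) and pig 9485 high for CHI3L1 (0.901). At 1 year the artery difference of pig 9175 was high for SMPDL3A (0.767), that of pig 9192 high for ENPP2 (0.635), and pig 9237 was low for KIAA1644 (0.632). At 2 years the artery difference of pig 9006 was low for TPPP3 (0.834), and pig 9997 was high for HMMR (0.741). Each of these 8 pigs stood apart for 1 gene.

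By the test of artery by age the artery effect differed between the age groups for 260 genes with a symbol. The 8 with the smallest adjusted p were DKK1 (adjusted p = 0.000174), EFHD1 (0.000174), CLDN10 (0.000574), FHOD3 (0.000648), CYSLTR2 (0.000701), ENO3 (0.000718), LOC100621607 (0.000825) and SFRP1 (0.000842). The control probe sets of beta actin, which the gene tests did not use, had a 3' minus 5' signal that was higher by 0.333 at 2 years than at 1 year.

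Whether chance can give as many calls was asked with other splits of the samples. For the artery over all ages 1 of 100 splits, the real one, reached 2431 probe sets and the highest other gave 152. No other split drawn gave as many, but shares of this size cannot exclude chance. They were not adjusted over the comparisons. The same holds for artery by age, with 787 against 7. It holds at 1 year too, where 1 of 32 splits, the smallest share possible there, reached 1357 and the highest other 83. At 1 week the 8 splits are too few for a share under 0.05 (1697 against 5 in the highest other), and so are the 16 splits at 2 years (1545 against 300). Only the real split, 1 of 100 each, reached the count in the age comparisons. These were 1 year against 1 week (8692 against 1058), 2 years against 1 week (9674 against 7194) and 2 years against 1 year (6329 against 10). For 2 years against 1 week a wrong split of the pigs could thus give 7194, so the size of that count says less than in the other comparisons.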

How the results depend on the processing

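The alternatives that left out pigs 9994, 9995 and 9997 and that added the actin signal were chosen after seeing the data. Of 3397 values of 164 results on named genes, 3270 kept their direction and their side of the threshold, 58 fell short of it, 17 newly passed, 51 without a call moved and 1 reversed. Of 1454 values of 64 results on gene lists 1272 kept both, 181 fell short, 64 of them with an estimated correlation and 17 with fry, and 1 reversed. The 17 values of fry come from a test of another question, whether a list's genes shifted in a shared direction. The reversals were the log2 fold change of CXCL9 at 2 years against 1 year without the 3 pigs (-0.075) and cell cycle genes in femoral against brachial at 2 years without the lowest 50% of probe sets (adjusted p = 0.931). For the cell cycle genes only the direction of the test turned, and the median shrank but stayed positive (0.0488). The cause was not tested for either.

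Counts of called probe sets moved by more than 1.5 times as follows. Without the lowest 50% of probe sets, which tests fewer, 5353, 5566 and 4118 were called for 1 year against 1 week, 2 years against 1 week and 2 years against 1 year. Without the pig block the artery counts were 1329 over all ages, 525 at 1 week, 439 at 1 year and 100 at 2 years, and 12 for artery by age. The random block gave 677 at 2 years and 411 for artery by age. The title number gave 1061 over all ages, fits to an age alone, with fewer arrays, 871 at 1 week and 658 at 2 years, and brachial arrays alone 3953 for 2 years against 1 year. Without the 3 pigs the counts were 524 for the artery at 2 years, 241 for artery by age and 3217 for 2 years against 1 year. With the actin covariate they were 2906 for 2 years against 1 week and 1873 for 2 years against 1 year. Apart from fewer probe sets or arrays, the cause was not tested.

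Leaving out each pig in turn gave 1969 to 2512 for the artery over all ages, 805 to 1717 at 1 week, 941 to 1198 at 1 year, 724 to 1707 at 2 years and 292 to 1088 for artery by age. It gave 7681 to 8380 for 1 year against 1 week, 8753 to 10077 for 2 years against 1 week and 5155 to 6777 for 2 years against 1 year. No other scaling moved the median of all probe sets by more than 0.1 in these comparisons. Signals near the lowest values, such as those of APOB and ADIPOQ, limit what the arrays can show for such genes. The same holds for signals near the highest values, such as that of ACTA2.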

Other observations

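Some of the largest changes were in probe sets without a gene symbol. Between the arteries over all ages such a probe set had a log2 fold change of -2.99 ± 0.11, and another of 1.86 ± 0.18. At 1 year against 1 week a probe set without a symbol rose by 7.503 ± 0.08 and another fell by 6.88 ± 0.08. A probe set annotated to both EIF2S3 and LOC100624149, left out of the named genes for having 2 symbols, rose by 5.65 ± 0.13 in that comparison, close to the 5.37 of EIF1AY. These were chosen after their values were seen.

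The matrix proteases and inhibitors included 4 of 18 genes called higher in the femoral artery at 2 years (6 adjusted over the list alone), among them the cathepsins CTSD (1.37 ± 0.23) and CTSS (1.09 ± 0.21) and the plasminogen activator PLAU (0.54 ± 0.10). The list adjusted p = 0.00494 became adjusted p = 0.335 with an estimated correlation, and 0.138 without pigs 9994, 9995 and 9997. Of 18 vasoactive receptors and channels 3 were called lower (4 lower and 2 higher adjusted over the list alone), AGTR1 (-0.996 ± 0.11), the channel subunit KCNMB1 (-0.31 ± 0.06) and the serotonin receptor HTR2B (-0.78 ± 0.21). Their list adjusted p = 0.00175 became adjusted p = 0.335 with an estimated correlation, and 0.0617 without the 3 pigs.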
